A study of Mus musculus with 6 samples.

How the data were processed

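Total RNA of sorted skin cells from 3 melanoma and 3 tumor-free samples was sequenced as stranded, ribosomal RNA-depleted paired-end libraries, per the labels' protocols. The same protocols state that RNA integrity numbers were moderate to low, so that some of the RNA was partly degraded before library construction. The authors deposited raw counts of reads per Ensembl gene, 1 column per library, with no normalization. HISAT2 2.1.0, SAMtools 1.10, HTSeq 0.11.2, edgeR, R 4.0 and the mouse build GRCm38 are named in the submitters' processing notes. The annotation release, the strand setting of the counting and any read filter are not given in the sources used here. Strand was checked on the counts: over the 6 libraries Tsix, which is transcribed opposite to Xist, took 0.0221% of the counts of the pair. A deposited sequencer sample sheet holds no measurement and was not used.

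The table has 55487 genes, of which 55141 were paired with a symbol from the reference table of gene names. Genes without a symbol held 0.0465% of the counts. The table ends in 5 HTSeq entries that name no gene, and these were left out of library sizes and tests. Reads that were not aligned made up 30.5%, 44.4% and 12.1% of the HTSeq total in melanoma replicates 1, 2 and 3 and 28.4%, 14.1% and 9.93% in tumor-free replicates 1, 2 and 3. Reads aligned outside annotated exons (no feature) made up 30.5%, 20.6% and 40.0% against 26.3%, 30.9% and 32.3%. As a share of uniquely aligned reads they made up 49.0%, 48.2% and 50.4% against 41.5%, 40.4% and 40.7%. Reads with several alignments made up 4.41% to 10.1%, ambiguous reads 0.444% to 1.09% and reads of low alignment quality 2.68% to 3.89%. Between 21.7% and 46.0% of the HTSeq total was counted in genes. Gene counts summed to 13383079 to 37212607 per library, so that 3 counts, taken as the limit that a count of 0 allows, correspond to 0.0806 to 0.224 CPM. Wilson 95% intervals of the shares given for single libraries have a half-width of at most 0.0235 percentage points. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

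Samples were grouped by their titles. Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), scaled by TMM and tested with the robust quasi-likelihood F test in R 4.3.3, with the group as the only term. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. The SE of a log2 fold change is the one implied by the F statistic. Gene positions and biotypes come from GENCODE M21, which uses the same build GRCm38. CPM values of genes are on TMM-scaled library sizes, and sums over lists and the values of Ngfr, Plp1, Sox10 and S100b in raw counts are not scaled. Common dispersion corresponded to a biological coefficient of variation of 40.8%.

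The test, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The 16 biology lists and 17 cell type marker lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted within each of the 2 families, with an estimated correlation and fry beside it. Some lists share genes: 3 of the 12 fibroblast genes are also matrix genes, and 8 of the 20 repair Schwann cell genes, 4 of the 12 fibroblast genes and 6 of the 16 trophic factor genes stand in another list, while the mast cell and macrophage lists share none. The shares of 5 quality classes were compared by an exact two-sided permutation test, which cannot go below p = 0.1 for 3 against 3 libraries. The genes named were the 10 higher and 10 lower called genes with the largest fold change, a mean of at least 10 CPM in the higher group, no overlap between the groups and a named symbol. In each list, up to 4 called members of smallest p were named, or where none was called up to 2 members as values. Ngfr, Plp1, Sox10 and S100b were given in every library. Genes named outside this rule are said to be so.

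Alternatives were RLE and upper quartile scaling, no filter on low counts, at least 10 counts in 3 libraries, the replicate number as a block, removal of the quality classes and haemoglobin genes, each library left out in turn, DESeq2 1.42.0, limma-voom with sample weights, no robust estimation, a fold minimum of log2 1, an estimated correlation and fry. Thinning all libraries to the smallest depth, removal of genes on chromosomes X and Y and 5 further gene lists were added after seeing the data. Pairs of libraries were compared by a chi-square per gene. It was 15.8 to 23.4 between tumor-free libraries and 143 to 314 between melanoma libraries, so that none repeated another. Melanoma replicate 3 gave 126 with tumor-free replicate 1, less than with either other melanoma library. Sample weights from limma-voom were 0.293, 0.298 and 1.02 for the melanoma libraries and 2.03, 2.48 and 2.24 for the tumor-free libraries. The edgeR fit took no account of this unequal spread.

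The edgeR step was tested on simulated counts for the comparison of melanoma with tumor-free (15917 genes in the fit). It recovered 7.37% of 95 genes changed by a log2 fold change of 1 and 51.1% of 94 genes changed by 2, and 8.06% of its 62 calls were unchanged genes. In this simulation most changes of 2-fold were not called. Few genes were changed in it, which makes the adjusted threshold stricter than in the real comparison, where 1592 genes were called. Its recovery therefore does not give the share of 2-fold changes missed there. Both simulated groups were drawn with the same dispersion for each gene, while the real melanoma libraries differed more among themselves than the tumor-free libraries. The share of unchanged genes among the simulated calls therefore does not give the share of false calls in the real comparison.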

Results

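RNA was sequenced from cells sorted out of the digested back skin of mice and labelled as Schwann cells, the glia of peripheral nerves. The mice carried a tamoxifen-dependent Cre recombinase under the promoter of Plp1, a myelin protein gene, together with a Cre-activated red fluorescent reporter, and the cell suspension was stained for p75NTR, the receptor encoded by Ngfr. The 3 libraries of the melanoma group came from skin around B16F10 tumors, a transplantable mouse melanoma line, and the 3 libraries of the tumor-free group from mice without tumors. The comparison asks how the transcripts of skin Schwann cells next to a melanoma differ from those of Schwann cells in tumor-free skin. Gene counts summed to 21420818, 13383079 and 18966479 in melanoma replicates 1, 2 and 3, and to 25704801, 32655112 and 37212607 in tumor-free replicates 1, 2 and 3. The labels do not say whether replicates were separate mice, so the p-values measure the spread between these libraries. The Y-linked gene Ddx3y had 2589, 0 and 0 counts in melanoma replicates 1, 2 and 3, so these did not all come from the same mouse. Part of the spread may still be technical. Values for a gene are CPM, counts scaled to library size, with TMM scaling unless raw counts or unscaled sums are named, and fold changes are melanoma over tumor-free with their standard error (SE).

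All 6 libraries labelled Schwann cells held far more macrophage than Schwann cell transcripts. The 16 listed macrophage genes summed to 12547 ± 4994 CPM in the melanoma libraries and 25582 ± 586 CPM in the tumor-free libraries (unscaled, SD, n = 3 each). The 16 listed Schwann cell genes summed to 26.6 ± 7.90 and 21.1 ± 1.93 CPM, of which Erbb3 made up 35.4% and 69.9%. Without Erbb3 the sums were 11.9, 25.9 and 13.7 CPM in the melanoma libraries and 6.96, 4.13 and 7.93 CPM in the tumor-free libraries. In single libraries the macrophage sum was between 211 and 1392 times the Schwann cell sum, and between 280 and 6351 times the sum without Erbb3. Lyz2, the gene of lysozyme in myeloid cells, ranked 11 among all genes by mean unscaled CPM, Mrc1, a mannose receptor of tissue macrophages, ranked 14, and Csf1r, the receptor for the macrophage growth factor, ranked 29. Sox10, the transcription factor of glia and melanocytes (chromosome 15, 79154908 to 79165240 in GRCm38, protein coding), had 16 counts in melanoma replicate 2 and 0 counts in each of the other 5 libraries. A count of 0 allows up to 3 counts, or 0.0806 to 0.158 CPM in those libraries. Plp1 (chromosome X, 136822671 to 136839733) had 0, 6 and 15 counts in the melanoma libraries and 4, 12 and 13 counts in the tumor-free libraries. S100b, a calcium-binding protein of glia, had 4, 48 and 0 counts against 1, 2 and 3. Ngfr (chromosome 11, 95568818 to 95587735) had 131, 82 and 50 counts in the melanoma libraries and 15, 2 and 15 in the tumor-free libraries. Its log2 fold change was 3.58 ± 0.82 (SE; edgeR adjusted p = 0.0412), and its protein was the one stained before sorting. Of the 16 Schwann cell genes, 4 passed the filter on low counts. Erbb3, a neuregulin receptor, stood at 8.48 ± 2.23 against 16.2 ± 0.182 CPM (SD, n = 3; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0532), and Matn2, a matrix protein, at 2.55 ± 0.168 against 0.753 ± 0.233 CPM (adjusted p = 0.0656).

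**Figure D1:**
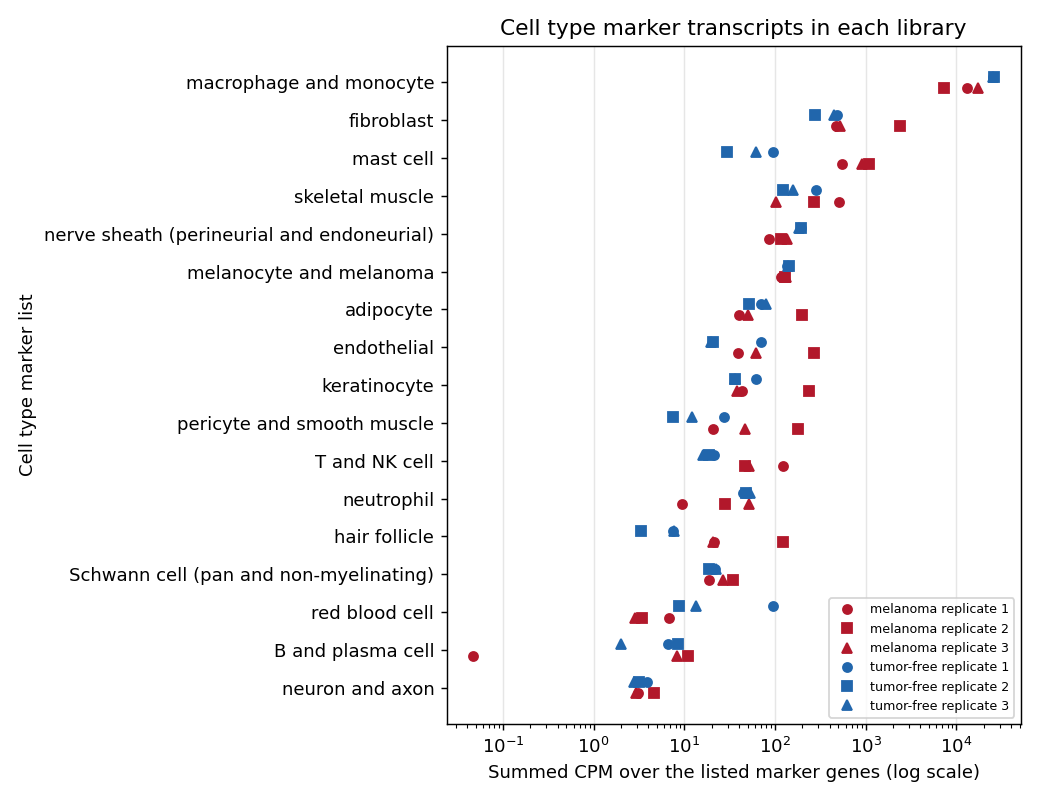
Summed CPM of the listed marker genes of 17 cell types (vertical axis) on a log scale (horizontal axis), 1 point per library, red for melanoma and blue for tumor-free, with the symbol giving the replicate. Macrophage genes lie highest in all 6 libraries, between 7270 and 26258 CPM, Schwann cell genes lie between 18.7 and 34.5 CPM, and melanoma replicate 2 has the highest fibroblast sum, 2391 CPM.

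Between the groups, 670 genes were higher and 922 lower in melanoma among 16461 genes tested, by the edgeR quasi-likelihood test at a Benjamini-Hochberg false discovery rate of 0.05. The mast cell proteases Cpa3 and Tpsb2 were among the 10 largest rises at 10 CPM or more, and the cytokine genes Il10, Il1a, Cxcl1 and Ccl7 among the 10 largest falls. The 3 libraries of one group lay entirely above those of the other for 40.5% of the genes tested, where 10% is the share chance gives. The split depended on scaling: upper quartile scaling gave 969 higher and 744 lower genes, and moved the median log2 fold change of all genes from 0.04 to 0.14. The counts also depended on single libraries. Without melanoma replicate 2, in which mitochondrial transcripts took 25.9% of the counts against 3.56% to 6.58% in the other libraries, 1274 genes were higher and 1240 lower. Without tumor-free replicate 1 the counts fell to 26 and 62. Without tumor-free replicate 2 or 3 edgeR called 0 genes, with 3055 and 3274 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.0589 and 0.0734, while DESeq2 called 1412 and 1650 genes on the same libraries and limma-voom with sample weights 1893 and 2006. All of the 1592 called genes with a value in those fits kept their direction without any 1 of the tumor-free libraries.

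Mast cell genes rose together in melanoma. All 8 listed genes, which encode granule proteases, the high-affinity IgE receptor and histamine synthesis, passed the test, both over all genes and adjusted over the list alone, with a median log2 fold change of 3.56. Mcpt4, a mast cell chymase, stood at 199.5 ± 53.7 CPM in melanoma and 17.0 ± 7.79 CPM in tumor-free libraries (SD, n = 3 each), a log2 fold change of 3.56 ± 0.39 (SE; edgeR adjusted p = 0.00837). Cma1, another chymase, rose 11.5-fold, Tpsb2, a tryptase, 11.8-fold, and Cpa3, the mast cell carboxypeptidase (chromosome 3, 20215620 to 20242181), 12.5-fold. The list passed camera with its preset correlation (adjusted p = 4.4e-15) and gave an adjusted p = 0.235 with an estimated correlation. Without melanoma replicate 3, or without tumor-free replicate 1, edgeR called 5 of the 8, and without tumor-free replicate 2 or 3 it called 0, with all 8 at an unadjusted p under 0.05 and all 8 called by DESeq2 in both cases. The summed mast cell genes held 554, 1094 and 903 CPM in the melanoma libraries and 94.5, 29.4 and 61.7 CPM in the tumor-free libraries (unscaled), so they were a small part of the counts in both groups.

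The 10 genes with the highest called rises at 10 CPM or more included Cpa3 and Tpsb2. The vesicular monoamine transporter Slc18a2 (chromosome 19, 59260896 to 59296012, protein coding) rose most, 17.8-fold, from 0.974 ± 0.747 to 17.2 ± 5.62 CPM (SD, n = 3; log2 fold change 4.16 ± 0.67 SE, edgeR adjusted p = 0.019). The serotonin transporter Slc6a4 rose from 2.07 to 24.6 CPM, the transcription factor Gata2 13.1-fold, and the Mas-related receptors Mrgprx2 and Mrgprb1 16.3-fold and 13.5-fold. These receptors belong to a family of closely related genes, so their counts are uncertain. Hs6st2, a heparan sulfate sulfotransferase, rose 12.2-fold and Adgrg5, an adhesion receptor, 14.1-fold. Slc18a2, Slc6a4, Gata2, Mrgprx2, Mrgprb1 and Hs6st2 stand in a list of further mast cell genes, given below, so these rises overlap with the mast cell rise. Alox15, a lipoxygenase that oxidizes arachidonic and linoleic acid, rose 15.2-fold (adjusted p = 0.0282), with 40.2, 5.55 and 11.3 CPM in the melanoma libraries. Without melanoma replicate 1 Alox15 was 6.69-fold higher, and without tumor-free replicate 1 Slc18a2, Gata2 and Slc6a4 were 28.2-fold, 21.0-fold and 19.7-fold higher (edgeR adjusted p = 0.0608, 0.0505 and 0.0404). Alox15 was the 1 called gene among 15 measured genes of eicosanoid synthesis, and that list as a whole did not pass camera (adjusted p = 0.587).

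**Figure D2:**
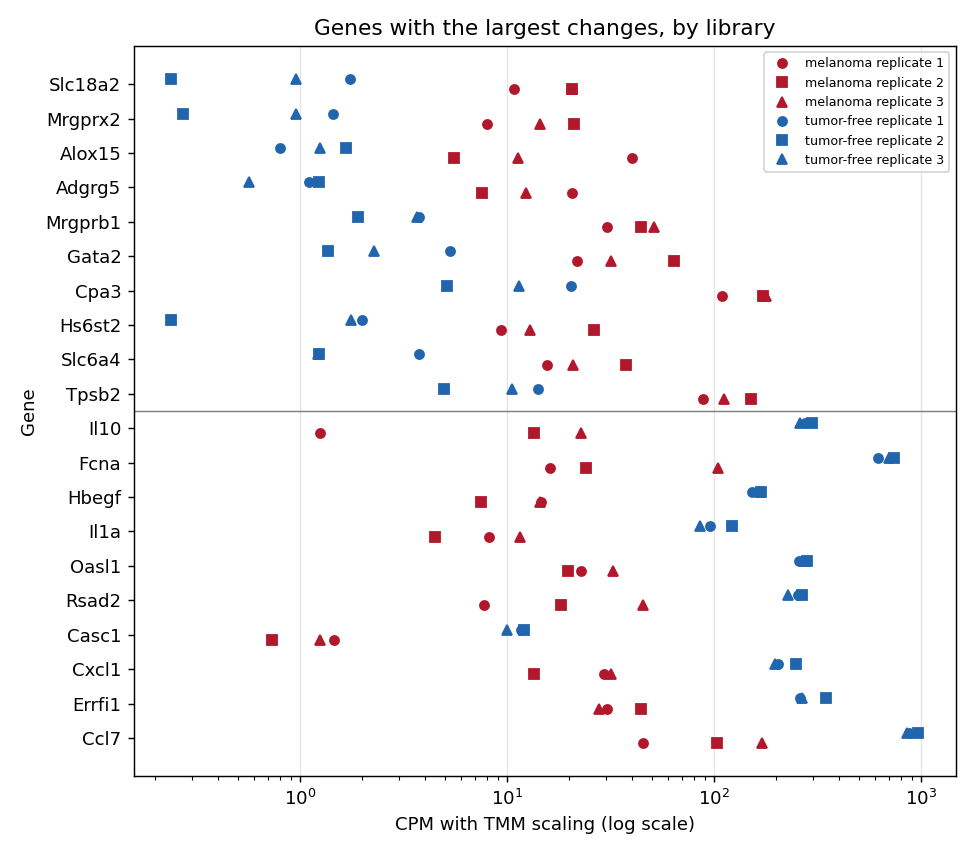
CPM with TMM scaling on a log scale (horizontal axis) of the 10 genes with the largest called rises and the 10 with the largest called falls (vertical axis, above and below the line), 1 point per library, red for melanoma and blue for tumor-free, with the symbol giving the replicate. In each of these genes the 3 libraries of one group lie apart from the 3 of the other, as they do by the rule that chose them. Cpa3 averages 153.6 against 12.3 CPM and Il10 12.5 against 277 CPM.

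Immediate early genes are switched on within minutes of a stimulus. They were listed together with genes of the response to tissue dissociation, heat shock genes among them. The joint list is called the immediate early list here and below. Of 23 measured genes 16 fell in melanoma and 1 rose, and adjusted over the list alone 17 fell and 3 rose. Egr1, a zinc finger transcription factor (chromosome 18, 34859823 to 34864984), fell from 1355 ± 36.5 to 263 ± 32.2 CPM (SD, n = 3), a log2 fold change of -2.36 ± 0.19 (SE; edgeR adjusted p = 0.00642). Ier3 was 8.12-fold lower, Btg2, an antiproliferative factor, 3.98-fold lower, and Zfp36, which destabilizes cytokine mRNAs, 3.61-fold lower. The gene that rose, named after its value was seen, was the heat shock gene Hspa1b, at 1026 ± 255 against 395 ± 27.7 CPM (log2 fold change 1.38 ± 0.23 SE). Hspa1b has a near-identical copy, Hspa1a, so its counts are uncertain. The list passed camera (adjusted p = 2.8e-19) and gave an adjusted p = 0.0534 with an estimated correlation. With tumor-free replicate 1, 2 or 3 left out edgeR called 3, 0 and 0 of the 23 genes as falling, with 17 lower at an unadjusted p under 0.05 in each case and 17, 15 and 16 by DESeq2. The macrophage list was lower in the same libraries, with a median log2 fold change of -1.44 against -1.43 for the immediate early list.

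Of 26 measured chemokine and cytokine genes 10 fell and none rose, and adjusted over the list alone 13 fell. Il1a, an alarm cytokine, was 12.4-fold lower, Cxcl1, a neutrophil attractant, 8.66-fold, Tnf 4.14-fold and Il6 4.04-fold. Il10, an anti-inflammatory cytokine (chromosome 1, 131019845 to 131024974), had the largest fall of the genes at 10 CPM or more, from 277 ± 18.4 to 12.5 ± 10.8 CPM (SD, n = 3), a log2 fold change of -4.48 ± 0.88 (SE; edgeR adjusted p = 0.0277). Ccl7, a monocyte attractant, was 8.45-fold lower. Of the 33 lists tested, this was the 1 list that passed camera with both the preset and an estimated correlation (adjusted p = 2.3e-10 and 0.0279). Without tumor-free replicate 1, 2 or 3 edgeR called 4, 0 and 0 of the 26 genes as falling, with 14, 13 and 14 lower at an unadjusted p under 0.05 and 12, 11 and 11 by DESeq2, and without melanoma replicate 2 it called 15. The macrophage list was lower in the same libraries, with a median log2 fold change of -1.44 against -1.50 for the cytokine list. Without melanoma replicate 3 Il10 was 39.5-fold and Fcna 34.6-fold lower. Other genes among the 10 largest falls were Fcna, a ficolin of macrophages, 14.2-fold lower, Hbegf, a ligand of the EGF receptor, 13.3-fold, Errfi1, an inhibitor of that receptor, 8.56-fold, and Casc1, 9.64-fold.

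Parts of the interferon, MHC class I and checkpoint lists fell in melanoma. The macrophage list was lower in the same libraries, with a median log2 fold change of -1.44 against -1.32 for the interferon, -0.50 for the class I and -0.82 for the checkpoint list. Of 21 interferon response genes 6 fell, and adjusted over the list alone 14. Rsad2, an antiviral enzyme, was 10.5-fold lower, Ifit1 5.03-fold, Irf1 2.49-fold and Stat1 1.98-fold. Oasl1, outside that list and also interferon-induced, was 10.8-fold lower. The list passed camera (adjusted p = 5.2e-09) but not with an estimated correlation (adjusted p = 0.345), and edgeR called 14 of its genes without melanoma replicate 1 and 4 without melanoma replicate 2. Without melanoma replicate 3 Rsad2 was 19.6-fold lower. For the interferon list edgeR called 0 genes without tumor-free replicate 1, 2 or 3, with 14 lower at an unadjusted p under 0.05 in each case and 11, 7 and 9 by DESeq2. Of 13 MHC class I genes 5 fell, and adjusted over the list alone 7. B2m, the shared light chain, went from 1428 ± 131 to 487 ± 97.4 CPM (SD, n = 3; edgeR adjusted p = 0.0145), H2-K1 was 1.98-fold lower, the peptide-loading factor Tapbp 2.19-fold and H2-T23 2.03-fold. H2 class I genes are close paralogs, so their counts are uncertain. That list passed camera (adjusted p = 4.3e-05) and gave adjusted p = 0.242 with an estimated correlation. Among class I genes edgeR called 0 without tumor-free replicate 1, 2 or 3, with 7, 6 and 6 lower at an unadjusted p under 0.05 and 5 by DESeq2 in each case. Of 11 MHC class II genes 2 rose and 2 fell, and the same numbers were called adjusted over the list alone. Ciita, the transactivator of class II genes, rose 2.77-fold and H2-DMb2 7.17-fold, while the costimulatory genes Cd86 and Cd40 were 3.16-fold and 4.48-fold lower. Without melanoma replicate 1 H2-DMb2 was 3.30-fold higher. The class II list did not pass camera (adjusted p = 0.832), and without tumor-free replicate 1, 2 or 3 edgeR called 0 of its genes, with 2 higher and 2 lower at an unadjusted p under 0.05 and by DESeq2 in each case. Of 12 measured immune checkpoint genes 4 fell and 1 rose, and adjusted over the list alone 7 fell and 1 rose. The ectonucleotidase Entpd1 was 2.39-fold and the galectin Lgals9 1.73-fold lower, and the PD-1 ligand Pdcd1lg2 rose from 0.301 ± 0.0371 to 2.44 ± 1.28 CPM (edgeR adjusted p = 0.0326). This list, which shares Il10 and Tgfb1 with the cytokine list, passed camera (adjusted p = 0.0237) but neither with an estimated correlation (adjusted p = 0.242) nor without melanoma replicate 3 (adjusted p = 0.0734). Without tumor-free replicate 1, 2 or 3 edgeR called 0 of its genes, with 7, 7 and 6 lower and 1 higher at an unadjusted p under 0.05 and 4, 2 and 4 lower and 1 higher by DESeq2.

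Of 16 measured macrophage genes 6 fell in melanoma, and adjusted over the list alone 12, with a median log2 fold change of -1.44. Cd14, a receptor for bacterial lipopolysaccharide, fell from 958 ± 152 to 139 ± 16.6 CPM (SD, n = 3; log2 fold change -2.78 ± 0.21 SE, edgeR adjusted p = 0.00642). The complement genes C1qa and C1qb were 4.64-fold and 3.34-fold lower and Csf1r 3.43-fold. The list passed camera (adjusted p = 1.9e-10) and gave adjusted p = 0.235 with an estimated correlation. Without tumor-free replicate 1, 2 or 3 edgeR called 1, 0 and 0 of the 16 genes as falling, with 9, 8 and 8 lower at an unadjusted p under 0.05 and 8 by DESeq2 in each case. Without melanoma replicate 3 C1qa was 7.01-fold lower. Of 15 phagocytosis and lipid handling genes 4 fell, and adjusted over the list alone 5. They were the apoptotic cell receptor Mertk, 2.77-fold lower, its bridging ligand Pros1, 3.31-fold, the cholesterol exporter Abca1, 3.90-fold, and the scavenger receptor Cd36, 2.15-fold. That list passed camera (adjusted p = 0.0236) but not with an estimated correlation (adjusted p = 0.345), and without melanoma replicate 2 it did not pass (adjusted p = 0.157) and 1 of its genes fell and 1 rose. Without tumor-free replicate 1, 2 or 3 edgeR called 0 of its genes, with 6 lower at an unadjusted p under 0.05 in each case and 5, 4 and 5 by DESeq2.

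Of 21 cell cycle genes 7 rose in melanoma, and adjusted over the list alone 13, with a median log2 fold change of 1.60. In the same libraries the macrophage list had a median of -1.44. The T and NK cell list held 124, 46.6 and 51.4 CPM in the melanoma libraries against 16.2 to 21.2 CPM in tumor-free libraries (unscaled). Cd2 made up 87.9% and 74.8% of that sum in the groups. Without Cd2 the sums were 4.01, 13.3 and 9.54 CPM against 4.55, 3.55 and 6.05 CPM. Cenpf, a kinetochore protein, rose from 8.86 ± 3.42 to 38.4 ± 8.35 CPM (SD, n = 3; log2 fold change 2.12 ± 0.31 SE, edgeR adjusted p = 0.015), the cyclins Ccnb1 and Ccna2 rose 5.18-fold and 4.38-fold, and the mitotic kinase Cdk1 3.04-fold. The summed genes of the list held 1479 CPM in melanoma replicate 1, against 559 and 756 CPM in the other melanoma libraries and 379 ± 34.4 CPM in the tumor-free libraries (unscaled, SD, n = 3). The list passed camera (adjusted p = 1.2e-07) and gave adjusted p = 0.47 with an estimated correlation and 0.152 with fry. Without melanoma replicate 2 edgeR called 11 of its genes, and without melanoma replicate 1 the median was 0.78. The calls numbered 1, 0 and 0 without tumor-free replicate 1, 2 or 3, with 13, 11 and 10 higher at an unadjusted p under 0.05 and 11, 7 and 7 by DESeq2. Extracellular matrix genes had a median log2 fold change of 1.25, which was 0.21 without melanoma replicate 2, and of the 22 none passed the edgeR test, over all genes or adjusted over the list alone. Postn, a matricellular protein, was at 59.8 ± 83.1 against 4.19 ± 1.22 CPM (SD, n = 3; adjusted p = 0.0726), and Timp1, a metalloproteinase inhibitor, at 1.36 ± 0.286 against 3.42 ± 0.941 CPM (adjusted p = 0.0955). The summed list held 21207 CPM in melanoma replicate 1, 5020 and 7240 CPM in replicates 2 and 3 and 2670 ± 62.7 CPM in the tumor-free libraries (unscaled), but Fn1, the fibronectin gene, made up 87.5% and 76.9% of it in the groups. Without Fn1 the sum was highest in melanoma replicate 2, at 2888 CPM against 521 and 768 CPM in replicates 1 and 3 and 617 ± 119.6 CPM in the tumor-free libraries. The list passed camera (adjusted p = 0.0237) but neither with an estimated correlation (adjusted p = 0.897), nor with fry (adjusted p = 0.566), nor with upper quartile scaling (adjusted p = 0.0556), nor without melanoma replicate 2 (adjusted p = 0.567) or tumor-free replicate 2 (adjusted p = 0.0627).

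The lists of Schwann cell states gave mixed results. Since the libraries held few Schwann cell transcripts, calls in these lists cannot be assigned to Schwann cells. Of 20 repair Schwann cell genes, the set that Schwann cells switch on after nerve injury, 10 passed the filter on low counts. The adhesion molecules Ncam1 and L1cam rose 7.84-fold and 3.27-fold, and Jun, the transcription factor of that program and also an immediate early gene, was 2.30-fold lower (edgeR adjusted p = 0.0163). Adjusted over the list alone 3 rose and 2 fell, and the list did not pass camera (adjusted p = 0.296). Of 20 myelin genes 11 were measured. Mag, a myelin-associated glycoprotein that was at 9.79 ± 7.02 against 1.76 ± 0.085 CPM, rose 5.56-fold (3.22-fold without melanoma replicate 1). L1cam and Mag were highest in melanoma replicate 1, at 43.4 and 17.9 CPM, where Sox10 and Plp1 had 0 counts. Ncam1 was at 11.0 CPM in melanoma replicate 2, where Sox10 had 16 counts. In replicates 1 and 3, where Sox10 had 0 counts, Ncam1 was at 10.4 and 6.84 CPM. Pmp22 and Cnp, which are not restricted to glia, were 4.49-fold and 1.55-fold lower. Adjusted over the list alone 2 rose and 2 fell, and the list did not pass camera (adjusted p = 0.901), whose direction was down where the median and mean log2 fold changes were 0.10 and 0.18. Among 9 measured trophic and growth factor genes, Pdgfb rose 2.86-fold and Clcf1 2.46-fold, and adjusted over the list alone 2 rose and 1 fell. Without melanoma replicate 1 edgeR called 1 trophic gene as rising and 1 as falling. That list did not pass camera (adjusted p = 0.832), whose direction was up, as was the mean of 0.04, where the median was -0.16. With tumor-free replicate 1, 2 or 3 left out edgeR called 1, 0 and 0 repair genes and 0 myelin and trophic genes. At an unadjusted p under 0.05 there were then 5, 3 and 6 repair, 5, 4 and 4 myelin and 3, 2 and 3 trophic genes, and DESeq2 called 3, 3 and 4, 4, 2 and 2, and 1, 2 and 1.

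Of 17 hypoxia and glycolysis genes 1 rose, Ankrd37, 7.98-fold (4.56-fold without melanoma replicate 1, edgeR adjusted p = 0.0655), and 1 fell, P4ha1, a collagen prolyl hydroxylase, 1.89-fold lower, and adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.81). Of 12 genes of mesenchymal transition 1 fell, Tgfbi, a matrix protein, 2.12-fold lower, and the same number fell adjusted over the list alone (camera adjusted p = 0.832). None of the 20 cholesterol synthesis genes passed the edgeR test, over all genes or over the list alone (camera adjusted p = 0.832). Without melanoma replicate 1 edgeR called 2 of them as falling, and their median log2 fold change was -0.32 against 0.17 with all libraries. Lss, lanosterol synthase, was at 18.7 ± 3.25 against 13.6 ± 1.03 CPM and Insig1 at 79.9 ± 42.0 against 147.8 ± 7.67 CPM (SD, n = 3).

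**Figure D3:**
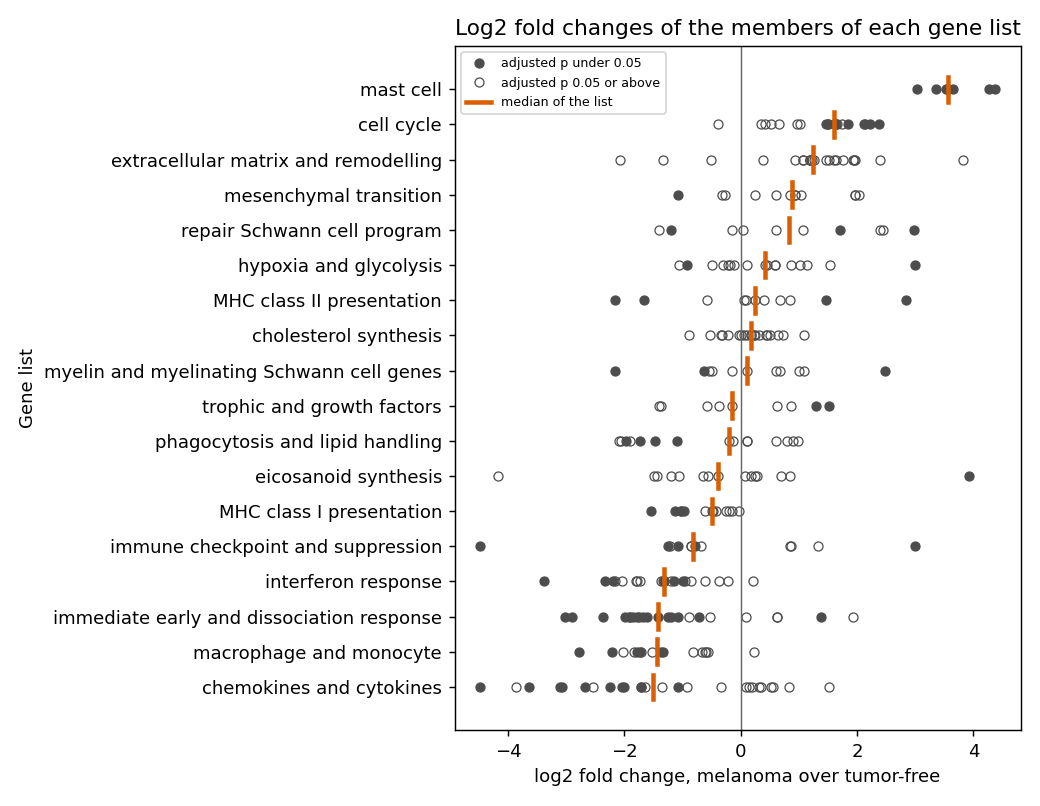
Log2 fold change of melanoma over tumor-free (horizontal axis) of each measured gene of the 16 biology lists and of the mast cell and macrophage lists (vertical axis), with filled points for genes at an edgeR adjusted p under 0.05, open points for the others and an orange bar at each list's median. The mast cell list has the highest median, 3.56, and the cytokine list the lowest, -1.50.

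Marker genes of further skin cell types lay higher in melanoma replicate 2 than in the other libraries. The fibroblast list held 2391 CPM there against 273 to 519 CPM elsewhere (unscaled), the endothelial list 272 against 19.6 to 69.8 CPM, the pericyte and smooth muscle list 179.5 against 7.47 to 46.6 CPM and the keratinocyte list 240 against 35.9 to 62.1 CPM. Of 11 measured hair follicle genes 3 rose, and 8 adjusted over the list alone. Msx2 had 57 counts over the melanoma group and 0 over the tumor-free group, at least 33.8-fold higher against a floor of 3 counts over the group. Tchh, the gene of a hair root sheath protein, rose 7.64-fold, and Dlx3, at 9.87 CPM in melanoma replicate 2 against 1.07 and 1.38 CPM in replicates 1 and 3, was also called. The hair follicle list passed camera (adjusted p = 0.000119) and gave adjusted p = 0.789 with an estimated correlation, and without melanoma replicate 3 1 of its genes rose. Without melanoma replicate 2 Tchh was 3.61-fold and Dlx3 13.2-fold higher (edgeR adjusted p = 0.0305 and 0.0657), and Dlx3 was 43.0-fold higher with all libraries and 89.7-fold without tumor-free replicate 3 (adjusted p = 0.158). In the hair follicle list edgeR called 0 genes without tumor-free replicate 1, 2 or 3, with 6, 7 and 10 higher at an unadjusted p under 0.05 and 7, 6 and 10 by DESeq2. The endothelial and the pericyte lists passed camera (adjusted p = 0.0455 and 0.0241) with no gene called by edgeR in either, over all genes or over the list alone. Neither passed with an estimated correlation (adjusted p = 0.789 for both), without melanoma replicate 2 (adjusted p = 0.711 and 0.329) or with upper quartile scaling (adjusted p = 0.107 and 0.0558), and the endothelial list also did not pass without tumor-free replicate 2 (adjusted p = 0.0717) or 3 (adjusted p = 0.0684) or after thinning to equal depth (adjusted p = 0.163). With fry the hair follicle, endothelial and pericyte lists gave adjusted p = 0.236, 0.495 and 0.381. Values in these lists were 19.7 ± 14.6 against 5.54 ± 4.79 CPM for Flt1, 1.57 ± 1.55 against 0.156 ± 0.199 for Emcn, 15.7 ± 22.1 against 1.81 ± 0.677 for Acta2 and 9.88 ± 12.5 against 1.49 ± 1.01 for Tagln (SD, n = 3).

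The remaining 12 marker lists did not pass camera, with the Schwann cell list at an adjusted p = 0.515. In the melanocyte list Mitf, a transcription factor that macrophages and mast cells also express, was 1.56-fold lower, and the summed list held 127 ± 8.18 against 139 ± 3.69 CPM (unscaled), of which Mitf made up 82.6% and 96.1% (camera adjusted p = 0.515). Without Mitf the sums were 11.9, 44.1 and 9.96 CPM in the melanoma libraries and 3.03, 4.13 and 9.19 CPM in the tumor-free libraries. Of the 5 measured melanocyte genes 4 had a positive log2 fold change, and the median was 1.25. The fibroblast list gave a camera adjusted p = 0.142, with Col1a1 at 337 ± 399 against 99.1 ± 30.4 CPM and Col3a1 at 289 ± 245 against 126.8 ± 27.3 CPM. The keratinocyte list gave 0.247, with Trp63 at 8.74 ± 7.88 against 1.05 ± 0.648 and Krt5 at 13.1 ± 13.6 against 1.85 ± 1.06 CPM. The nerve sheath list gave 0.47 in the upward direction, and 6 of its 8 measured genes had a positive log2 fold change. The 2 negative ones were Etv1 at 51.7 ± 35.9 against 188.9 ± 4.68 and Osr2 at 0.632 ± 0.152 against 2.21 ± 0.379 CPM. Etv1 made up 51.3% and 90.1% of the summed list in the groups. Without Etv1 the sum was 55.0 ± 18.4 against 18.8 ± 0.587 CPM (unscaled, SD, n = 3). The skeletal muscle list gave 0.537, with Ryr1 at 48.5 ± 34.9 against 19.7 ± 3.75 and Neb at 21.3 ± 11.95 against 10.6 ± 5.56 CPM. The adipocyte list gave 0.91 in the downward direction against a positive median of 0.64, with Fabp4 at 30.3 ± 40.2 against 9.74 ± 3.59 and Pnpla2 at 32.0 ± 6.61 against 43.0 ± 5.61 CPM. In 5 lists 2 genes each passed the filter on low counts. These were Csf3r at 24.7 ± 19.1 against 50.3 ± 3.90 and Ltf at 1.40 ± 0.698 against 0.324 ± 0.489 CPM for neutrophils (0.92), and Cd2 at 59.3 ± 44.0 against 15.4 ± 3.70 and Cd4 at 6.19 ± 3.65 against 4.21 ± 0.871 CPM for T and NK cells (0.259, and 0.00587 with fry). B and plasma cells (0.601) had Cd79b at 0.40 ± 0.692 against 1.71 ± 0.562 and Jchain at 5.44 ± 5.32 against 4.16 ± 3.93 CPM. Neurons (0.515) had Elavl4 at 0.311 ± 0.538 against 2.63 ± 0.206 and Tubb3 at 0.88 ± 0.924 against 0.572 ± 0.26 CPM. Red blood cells (0.183) had Alas2 at 2.59 ± 1.11 against 25.8 ± 33.2 and Hbb-bs at 1.098 ± 1.20 against 12.9 ± 14.8 CPM. Adjusted over the list alone, 2 Schwann cell genes rose and 1 fell, 1 nerve sheath gene rose and 2 fell, 1 melanocyte gene fell, 1 T and NK cell gene rose and 2 red blood cell genes fell.

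Several classes of transcript that reflect RNA quality and composition differed between the libraries. Mitochondrially encoded genes took 11.6 ± 12.4% of the counts in melanoma and 5.68 ± 1.16% in tumor-free libraries (SD, n = 3; exact two-sided permutation test, p = 0.9), and the difference of 5.95 percentage points was -1.20 without melanoma replicate 2. Nuclear-retained long RNAs took 2.92 ± 0.196% against 1.96 ± 0.0908%, small structural RNAs 0.114 ± 0.0713% against 0.297 ± 0.0168% and histone genes 0.0527 ± 0.00975% against 0.0365 ± 0.000875%, each with an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow. Ribosomal protein genes took 1.15 ± 0.357% against 0.982 ± 0.022% (exact permutation p = 0.5), a difference that also changed sign without melanoma replicate 2. Among uniquely aligned reads 49.2 ± 1.15% against 40.9 ± 0.585% lay outside annotated exons (SD, n = 3; exact permutation p = 0.1). Sex-linked genes were not balanced between the groups. Melanoma replicates 2 and 3 had 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and 65761 and 72598 counts of Xist, the RNA of the inactive X chromosome. Melanoma replicate 1 and the tumor-free libraries had 2589 to 5442 counts of Ddx3y. Xist had 420 counts in melanoma replicate 1 and 3881, 11022 and 8 counts in tumor-free replicates 1, 2 and 3. Tumor-free replicates 1 and 2 thus held both Y-linked and Xist counts, and whether a library mixes mice of both sexes is not given in the labels.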

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

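The tests of explanations below were all chosen after the results they weigh were seen, except the count of other splits of the libraries.

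Reads that were not aligned are outside the gene counts and were not compared in the report. They made up 44.4% of the HTSeq total in melanoma replicate 2 and 30.5% in melanoma replicate 1, above the highest share in a tumor-free library, 28.4%, while melanoma replicate 3, at 12.1%, lay below tumor-free replicates 1 and 2.

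The first pattern is that macrophage transcripts were abundant and Schwann cell transcripts near the floor in all 6 libraries. A reversed strand setting in the counting is argued against by the 0.0221% of Xist and Tsix counts that fell on Tsix. All 16 listed Schwann cell genes were among the genes counted, so none was missing from the annotation. Neither tests a loss of reads limited to Schwann cell genes. A strand setting acts on all genes, and a gene can be listed without counts. Schwann cells that keep their own transcripts and also carry macrophage transcripts are argued against for the tumor-free libraries, where the median of the 16 Schwann cell genes was at most 0.136 CPM and that of the macrophage list at least 1002 CPM (unscaled). A candidate explanation is that macrophages were among the sorted cells, although the staining for p75NTR would be expected to leave them out: the macrophage list had at least 2.28 times the mean CPM per gene of any other cell type list in each library, with Lyz2 at 5015 and Csf1r at 1871 CPM on average (unscaled). Cells that had lost Schwann cell transcripts altogether were not tested, since the table holds no measure of the reporter.

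The second pattern is the rise of mast cell genes in melanoma. A lower share of macrophages that raises all other cell types alike is argued against, since the mast cell list rose by 3.07 ± 0.696 (SE, log2) more than the fibroblast list, in every melanoma library above every tumor-free library. Other lists were not compared in this way, so the result holds against the fibroblast list. Of the other marker lists, only the hair follicle list had a higher median log2 fold change (4.55) than the mast cell list (3.56). A difference in sequencing depth is argued against, since after thinning to equal depth the median log2 fold change was 3.64 and 7 of the 8 genes were called. More mast cells among the sorted cells, with melanoma as the biological difference of the design, cannot be told apart from regulation within mast cells: the SD of 0.447 among the 8 log2 fold changes, against a median SE of 0.595, does not decide, since the genes share their spread between libraries (estimated correlation 0.753).

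The third pattern is the fall of 16 of the 23 immediate early genes in melanoma. The sex of the mice, which labels do not give and some libraries may mix, cannot be told apart from it: melanoma replicate 1, with Y-linked counts, had a median log2 difference of -1.36 from the tumor-free mean, against -1.55 and -1.49 in replicates 2 and 3, but it is the 1 such melanoma library. A lower share of macrophages cannot be told apart from it: the immediate early list fell by 0.417 ± 0.363 (SE, log2) less than the macrophage list, and 2 of 13 abundant macrophage genes, Itgam and Tyrobp, lay above the immediate early median by over 2 SE. In melanoma replicates 1, 2 and 3 the macrophage list summed to 13172, 7270 and 17199 CPM (unscaled). The immediate early list varied less, at 10708, 9092 and 10208 CPM, which 3 libraries leave undecided. Digestion, sorting time or day may also differ between the groups, and no label gives them, so this cannot be told apart from the melanoma effect for the 16 genes that fell.

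Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 1592 genes, and the highest of the other splits 0 (edgeR), so 1 of the 10 splits reached the real value. For gene lists, 1 of the 10 splits reached the real 8 lists, with 7 as the highest of the others. For marker lists, 8 of the 10 splits reached the real 5 lists, and the highest of the others had 11, with camera at its preset correlation. With an estimated correlation the real split called 0 marker lists. The count of marker lists therefore does not set the groups apart from other splits, and the cause was not tested.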

How the results depend on the processing

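Thinning and removal of X and Y genes were chosen after seeing the data, the other settings before. No called named gene or list turned its direction in any setting. The 69 called named genes were all kept by DESeq2, limma-voom and the fit without robust estimation, 68 by RLE and by upper quartile scaling, 64 of 68 after thinning, 7 with the block, 19 without tumor-free replicate 1 and none without tumor-free replicate 2 or 3. Genes higher and lower in melanoma numbered 1629 and 1619 with DESeq2, 1329 and 1676 with limma-voom, and 490 and 565 with a fold minimum, against 670 and 922. Leaving out each library in turn gave 0 to 1274 genes higher and 0 to 1305 lower. At 0, from edgeR without tumor-free replicate 2 or 3, 3055 and 3274 genes had an unadjusted p under 0.05, and DESeq2 called 1412 and 1650. Those fits have fewer samples, and the cause of the difference between edgeR and the other tools was not tested. With the replicate number as a block, 12 genes were higher and 17 lower. Same-numbered libraries did not deviate together (correlations of -0.13, -0.23 and -0.04), which gave no sign of pairing. Libraries of different numbers were not compared in this way, so pairing is not excluded. Of the 8 called gene lists, 1 held with an estimated correlation, and 6 were called by fry. Of the 17 marker lists, 5 were called, 3 with upper quartile scaling, 0 with an estimated correlation and 4 to 8 when each library was left out. Fry called 3: mast cell, macrophage and, not called by camera, T and NK cell (adjusted p = 0.00587). For camera at an estimated correlation the count of 0 compares with 5 at the preset correlation. Lists that were not called turned their direction as follows, and the cause was not tested: neutrophil with upper quartile scaling (adjusted p = 0.996) and without the filter (0.136), myelin (0.946) and neuron (0.832) without the filter. When each library was left out, uncalled lists that turned had adjusted p of 0.455 to 0.882 (MHC class II), 0.0266 to 0.999 (adipocyte), 0.121 to 0.937 (cholesterol), 0.231 to 0.933 (eicosanoid), 0.0176 to 0.746 (fibroblast), 0.204 to 0.834 (hypoxia), 0.0292 to 0.455 (keratinocyte), 0.547 to 0.937 (mesenchymal), 0.746 to 0.937 (myelin), 0.384 to 0.999 (neuron), 0.169 to 0.999 (neutrophil) and 0.023 to 0.936 (skeletal muscle). Uncalled lists were called in some settings: red blood cell with the block (adjusted p = 0.00165), without the filter (0.00545) and without tumor-free replicate 2 (0.0039) or 3 (0.042), fibroblast without the filter (0.0181) and without melanoma replicate 1 (0.0176) or 3 (0.0221), repair Schwann cell without the filter (0.0318), melanocyte without tumor-free replicate 3 (0.042), adipocyte without melanoma replicate 2 (0.0266), and keratinocyte (0.0292) and skeletal muscle (0.023) without melanoma replicate 3. Uncalled genes that turned had log2 fold changes of -0.40 to 2.14 (Fabp4), -0.53 to 1.27 (Jchain) and -0.45 to 1.23 (Tubb3). The difference in mitochondrial share was -1.20 to 9.98 percentage points and that in ribosomal protein share -0.00239 to 0.354, both negative without melanoma replicate 2.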

Other observations

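The 5 lists below were written after the values of some of their genes were seen, so their counts describe these libraries and are no independent evidence. Of 14 genes of resident dermal macrophages 5 fell in melanoma by the edgeR test, and all 14 had a negative log2 fold change, with a median of -1.98. Folr2, a folate receptor of resident macrophages, was at 126 against 1013 CPM, Mgl2, a galactose lectin, at 421 against 1192 CPM and the coagulation factor gene F13a1 at 2132 against 7348 CPM. In a list of monocyte-derived and dendritic cell genes 3 of 14 rose and 11 were positive. The negative ones were Ccr7, Zbtb46 and Kmo, at log2 fold changes of -3.44, -0.55 and -0.69, none of them called. Mmp12, a macrophage elastase, stood at 93.0 against 8.55 CPM, Itgax, an integrin of dendritic cells, at 127 against 26.6 CPM and H2-DMb2 at 91.7 against 12.8 CPM. Melanoma replicate 1 carried much of these means: the melanoma libraries held 186, 47.1 and 45.7 CPM of Mmp12, 227, 82.6 and 72.7 CPM of Itgax and 189.7, 44.6 and 41.0 CPM of H2-DMb2. With an estimated correlation these lists gave camera adjusted p of 0.0914 and 0.0841.

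Of 16 target genes of NF-kB 13 fell, with a median log2 fold change of -1.51 (camera adjusted p = 0.0392 with an estimated correlation). Cd83, an activation marker, was at 215 against 1193 CPM, Icam1 at 113 against 363 CPM and the inhibitor gene Nfkbia at 243 against 772 CPM. Of 18 lysosomal genes 11 fell (adjusted p = 0.111 with an estimated correlation), with Ctsb, a cathepsin, at 1670 against 7603 CPM and Lamp1 at 454 against 1549 CPM. Of 10 measured further mast cell genes 9 rose, with a median log2 fold change of 3.60 (camera adjusted p = 0.0392 with an estimated correlation). Among them was Kit, the stem cell factor receptor, at 71.3 against 6.90 CPM. That list includes Slc18a2, Slc6a4, Gata2, Mrgprx2, Mrgprb1 and Hs6st2, already named among the largest rises, so much of its result was known beforehand. The macrophage list was lower in the same libraries, and the lists above do not separate a change within macrophages from a change in their number.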
